A study of Mus musculus with 13 samples.

How the data were processed

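Total RNA from mouse embryonic stem cells (ESC) carrying a green fluorescent reporter of Stella, and from day 7 embryoid bodies grown from such cells, was measured on 13 Affymetrix Mouse430_2 arrays, 1 array per sample. The labels place the arrays in 5 groups: Stella-negative ESC (n = 3), Stella-positive ESC (n = 2), unsorted ESC (n = 2), Stella-negative day 7 cells (n = 2) and Stella-positive day 7 cells (n = 4). Stella is the protein made by Dppa3. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

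The deposited table holds linear MAS5 signal intensity per probe set for 45101 probe sets, per the submitters' processing notes; the MAS5 version, target intensity and scaling are not given in the sources used here. MAS5 subtracts background and mismatch signal by its construction. The array description files, written by the Affymetrix software, gave the chip type, chip lot and hybridisation run and no expression values. The deposited intensity columns were not on a common scale: their trimmed means (2% trimmed from each end) differed 27.1-fold, from 8.48 on Stella-positive day 7 array 4 to 230.0 on Stella-negative ESC array 2. By a rule set before the data were examined, each column was therefore scaled to the common trimmed mean of 105.2. A constant c of 10.5, equal to 1/10 of that mean, was added before log2. Fold changes are therefore on the log2(signal + c) scale, and the constant shrinks the change of dim genes. Scaling did not give the arrays a common median, so dim probe sets can also be shifted between groups. The 64 control probe sets were left out, and 30023 of the remaining 45037 were kept because their signal exceeded the array's own median on at least 2 arrays. No columns were duplicates of each other (0 identical pairs).

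Gene symbols came from the platform annotation supplied for this work: 34945 probe sets carried 1 symbol, 932 several and 9160 none, and 0 symbols needed updating through their gene identifiers. A gene was represented by its probe set with 1 symbol and the highest mean signal over all arrays. This gave 18193 genes, of which 13992 were tested. Coordinates were not used here.

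All 13 arrays entered 1 linear model of group means in limma 3.58.1 (R 4.3.3), with eBayes and a trended prior variance (prior degrees of freedom 8.88). There were 7 contrasts: the Stella sort at day 7, the Stella sort in ESC, day 7 against ESC in each sorted fraction, the interaction of sort and culture, and unsorted ESC against each sorted ESC fraction. Errors are limma standard errors (SE). P-values were two-sided and adjusted by the Benjamini-Hochberg method over all 30023 probe sets within a contrast, and an adjusted p under 0.05 was called. The 23 gene lists were tested in each contrast with limma's camera on the representative probe sets, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 23 lists. The model, contrasts, lists and naming rule were fixed before the data were examined. The lists were early primordial germ cell, later germ cell and meiosis, pluripotency, primed epiblast, primitive streak and mesoderm, extraembryonic and definitive endoderm, neural ectoderm, blood and globin, endothelium, cardiac and muscle, trophoblast, Hox, imprinted, DNA methylation and chromatin, 2-cell-stage, proliferation, BMP, Nodal, Lin28 and let-7, immediate early and stress, fibroblast and feeder, epithelium, and glycolysis and hypoxia. Members absent from the named probe sets, such as Nanos3, Nanos2 and H19, were not analysed here.

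Genes were named by rule. For the sort and culture comparisons these were the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between groups, up to 3 called members per list, and a fixed set of germ cell and pluripotency genes. For the interaction and unsorted comparisons up to 5 genes per direction were taken. Where no gene passed, the smallest p-values were taken and given as not past the test. Genes outside this rule are described as chosen after their values were seen.

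Shared responses were measured as Pearson and Spearman correlations of log2 differences across genes, which are not independent replicates, with the overlap of calls set against the product of the 2 counts divided by the genes tested. On data simulated with 30023 probe sets, 16 of 100 changes of log2 size 1 and 85 of 100 of size 2 were recovered for the day 7 sort with 8 false calls, and 18 of 100 and 78 of 100 for the ESC sort with 7 false calls. The simulation changed 100 probe sets at each size and gave every array independent noise of the same spread. In the data 4926 probe sets were called in the day 7 sort and array weights ran from 0.224 to 2.15. These rates therefore do not give the power of the 2 sorts.

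The alternatives were another constant (1/50 and 1/4 of the trimmed mean), no filter and a stricter filter (60th percentile), quantile normalization, centring on the array median, only the arrays of the groups compared, a constant prior variance, array quality weights, the replicate number as a block, the hybridisation run as a block, 1 probe set per gene, the median of a gene's probe sets, and leaving out each array in turn. Added after the data were seen were leaving out Stella-positive day 7 arrays 3 and 4, the log2 Gapdh 3'/5' ratio of each array as a covariate, the numbers in the array headers, which differ from those of the titles on most arrays, as the block, an estimated correlation for the lists within hybridisation runs, a crossed block, and unsorted ESC as the reference of day 7 cells. The run was a fixed block for the 2 sorts and their interaction, where a run held both groups, and otherwise a random block with a fitted correlation of 0.252. The list test was not run with the random block, which camera does not take. Within groups the Gapdh ratio varied mainly among the 4 Stella-positive day 7 arrays (1.23 to 2.09), of which arrays 3 and 4 were also the dimmest. The covariate therefore cannot separate RNA quality from dim signal.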

Results

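The series asks how cells that carry the Stella reporter in day 7 embryoid bodies, which the submitters describe as germ cells made in culture, differ from reporter-negative cells and from embryonic stem cells (ESC). Expression was measured on 13 arrays: 3 of Stella-negative ESC, 2 of Stella-positive ESC, 2 of unsorted ESC, 2 of Stella-negative day 7 cells and 4 of Stella-positive day 7 cells. Before scaling, the trimmed mean signal ran from 151.0 to 230.0 on the sorted ESC arrays, from 78.1 to 80.8 on the unsorted ESC arrays, and was 51.4 and 63.4 on the negative day 7 arrays. On the positive day 7 arrays it was 82.9, 71.7, 29.1 and 8.48. Correlations between replicates ran from 0.965 to 0.971 in Stella-negative ESC and from 0.846 to 0.953 in Stella-positive day 7 cells, and were 0.959 in Stella-positive ESC, 0.940 in unsorted ESC and 0.923 in Stella-negative day 7 cells. The number of arrays per group limits the precision of all comparisons.

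Dppa3, which encodes Stella, followed the sort on every array. Its scaled signal was 941.2 and 1473 in Stella-positive ESC, against 139.3, 227.5 and 244.5 in Stella-negative ESC. Unsorted ESC lay in between at 299.5 and 324.4. At day 7 it was 806.8, 728.5, 1078 and 1138 in positive cells and 74.6 and 101.4 in negative cells.

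The 3'/5' ratio of the actin control probe sets, which rises when labelled RNA is short, differed with culture and with the sort. It was 1.12 to 1.23 on all ESC arrays, 5.48 and 5.85 on the Stella-negative day 7 arrays, and 2.04, 2.17, 4.89 and 5.16 on the Stella-positive day 7 arrays. The Gapdh ratio was 0.803 to 0.869 in ESC, 3.03 and 3.18 in negative and 1.23 to 2.09 in positive day 7 cells. All day 7 arrays were hybridised on 1 day, apart from all ESC arrays.

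**Figure D1:**
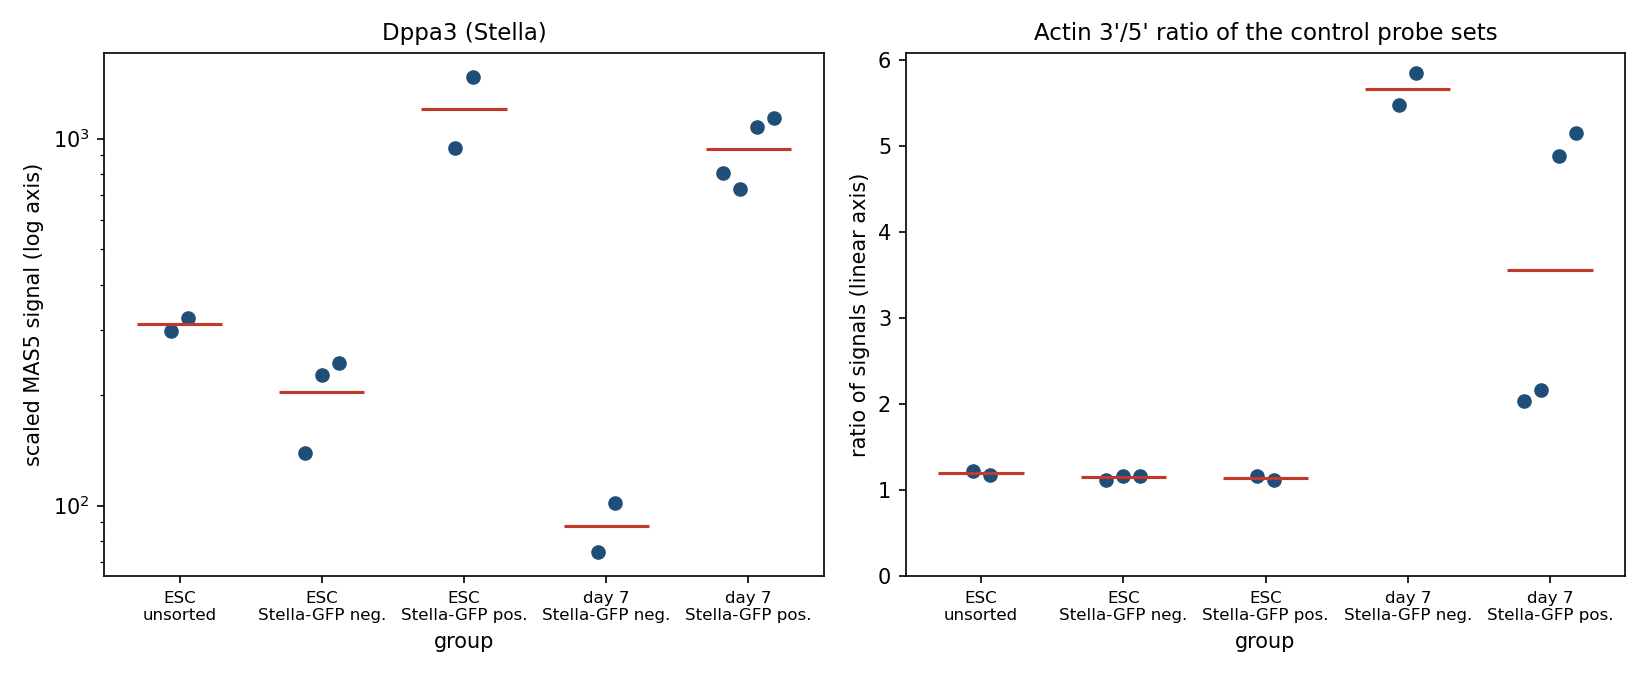
Scaled signal of Dppa3 on a log axis (left) and the actin 3'/5' ratio on a linear axis (right), with 1 point per array for the 5 groups and a line at each group's mean. The 6 Stella-positive arrays lie at 728.5 or more in Dppa3 signal, the other 7 arrays lie at 324.4 or less, and the Stella-negative day 7 arrays have the highest actin ratios, 5.48 and 5.85.

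At day 7, Stella-positive cells (n = 4) had higher later germ cell, pluripotency and cell cycle lists than Stella-negative cells (n = 2) and lower endoderm, mesoderm, blood, endothelium and cardiac lists. These 8 lists passed at a preset correlation between genes and lost their call with an estimated one (adjusted p from 0.0597 to 0.180). Dppa3 rose by 3.26 ± 0.26 (SE) on the log2 scale, the largest rise of all named genes. Smc1b, a meiotic cohesin subunit, rose by 2.86 ± 0.55, and Dmrt1, a transcription factor of germ cells and gonads, by 2.49 ± 0.37. The embryonic globin genes Hbb-y and Hbb-bh1 fell by 5.49 ± 0.77 and by 4.58 ± 0.62, and the yolk sac and liver genes Ttr and Afp fell by 4.65 ± 1.34 and by 4.19 ± 1.29. In all, 2564 probe sets were higher and 2362 lower at an adjusted p under 0.05, of which 1399 and 1926 changed at least 2-fold.

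Of 23 tested members of the later germ cell and meiosis list, 9 rose, 0 fell and 14 did not pass the test, with 10 higher when adjusted over the list alone. The risers included the germ cell RNA helicase Ddx4 (1.21 ± 0.34), the RNA-binding protein gene Dazl (1.19 ± 0.34) and the tudor-domain gene Rnf17 (1.82 ± 0.26). Against ESC of the same fraction, Ddx4 was called lower in negative day 7 cells and did not pass in positive ones. The list as a set was higher (camera adjusted p = 3.25e-06; adjusted p = 0.176 with an estimated correlation). Of 14 early primordial germ cell genes, 4 rose and 1 fell, or 6 and 1 adjusted over the list alone. Tfap2c, a transcription factor of primordial germ cells, rose by 2.01 ± 0.25 (adjusted p = 1.15e-04) and Alpl, the alkaline phosphatase used to stain such cells, by 1.28 ± 0.35. Sox17, an endoderm factor in the mouse, fell by 2.49 ± 0.69. Other genes of the early programme did not pass: Prdm1 was at -0.19 ± 0.26, Prdm14 at 0.86 ± 0.31, Dnd1 at 0.85 ± 0.31, Kit at 0.58 ± 0.26 and Ifitm3 at 0.52 ± 0.26. The set was higher (adjusted p = 0.0122; adjusted p = 0.280 with an estimated correlation), but it turned direction with the Gapdh ratio as a covariate (adjusted p = 0.810, with a range of 8.92e-05 to 0.810 over its alternatives).

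Of 27 pluripotency genes, 14 rose and 0 fell, with 16 higher when adjusted over the list alone. Pou5f1, a core pluripotency factor, rose by 1.72 ± 0.18, Dppa4 by 1.56 ± 0.22, Fbxo15 by 1.75 ± 0.30 and Sox2 by 1.09 ± 0.21, while Nanog was at 0.55 ± 0.26 (adjusted p = 0.166). Lin28a was at 0.52 ± 0.31 and its other probe set was called in the opposite direction. Of 23 proliferation genes, 17 rose and 0 fell (18 adjusted over the list alone), among them the replication licensing genes Mcm3 (1.30 ± 0.16) and Mcm6 (1.37 ± 0.18) and the mitotic cyclin Ccnb2 (1.29 ± 0.18). Of 22 DNA methylation and chromatin regulators, 12 rose and 0 fell (14 adjusted over the list alone), led by Dnmt3l, the cofactor of de novo methyltransferases, at 2.13 ± 0.28 and the arginine methyltransferase gene Prmt5 at 1.56 ± 0.21. The adjusted p-values of these 3 lists were 4.62e-09, 2.07e-09 and 3.25e-06, and adjusted p = 0.180, 0.119 and 0.0597 with an estimated correlation. These rises came with actin ratios of 5.48 and 5.85 on the negative arrays against 2.04 to 5.16 on the positive ones.

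The endoderm, mesoderm, blood, endothelium, cardiac, fibroblast and epithelium lists were lower in the Stella-positive cells. In the endoderm list 20 of 28 members fell and 0 rose (23 adjusted over the list alone), with Dab2 at -2.44 ± 0.41 and the basement membrane collagen Col4a1 at -1.76 ± 0.36. In the mesoderm list 11 of 23 fell (12 adjusted over the list alone), with Hand2 at -3.55 ± 0.54 and the VEGF receptor gene Kdr at -2.25 ± 0.44. The blood list had 5 of 16 lower (8 adjusted over the list alone), the endothelium list 7 of 16 (10), with Cd34 at -2.72 ± 0.59, and the cardiac list 9 of 16 (12), with Myocd, a cardiac and smooth muscle coactivator, at -3.13 ± 0.54. The adjusted p-values of these 5 lists were 2.29e-09, 1.66e-05, 4.28e-04, 4.28e-04 and 2.45e-05, and adjusted p = 0.119, 0.176, 0.0597, 0.180 and 0.180 with an estimated correlation. Fibroblast genes had 10 of 23 lower (15 lower and 1 higher adjusted over the list alone), with Col3a1 at -3.28 ± 0.48 (list adjusted p = 5.32e-06; adjusted p = 0.280 with an estimated correlation). Epithelial genes had 7 of 18 lower (12 and 1), with Krt8 at -2.25 ± 0.54 (list adjusted p = 7.18e-04; adjusted p = 0.374 with an estimated correlation). The negative arrays, on which all these lists were higher, also had the highest actin and Gapdh ratios.

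Of 25 imprinted genes, 15 fell and 0 rose (16 adjusted over the list alone), with the imprinted genes Dlk1 at -3.28 ± 0.44 and Peg3 at -2.89 ± 0.47 (list adjusted p = 4.97e-07; adjusted p = 0.0597 with an estimated correlation). Of 18 BMP targets and ligands 9 fell (11 adjusted over the list alone), with the inhibitor Smad6 at -2.37 ± 0.44 (list adjusted p = 3.26e-04; adjusted p = 0.119 with an estimated correlation). The Nodal list had 4 of 12 higher, among them Gdf3 at 1.45 ± 0.28 and Lefty1 at 0.71 ± 0.22, and did not pass as a set (adjusted p = 0.0647). In the trophoblast list Rhox5 (2.19 ± 0.31), Rhox6 (1.75 ± 0.32), Tex19.1 (1.65 ± 0.35) and 1 more rose and 3 members fell; its median was -0.53 and its mean 0.02, and the set test was in the upward direction without passing (adjusted p = 0.871). The glycolysis and hypoxia list likewise had 5 members higher and 1 lower of 19, a median of -0.29 and a mean of -0.12 with an upward test (adjusted p = 0.890). The Lin28 and let-7 list had 4 higher and 4 lower of 13, with a median of 0.25, a mean of -0.10 and an upward test (adjusted p = 0.871). The remaining lists did not pass: primed epiblast had 1 higher and 2 lower of 17 (adjusted p = 0.758), neural ectoderm 4 lower of 15 (0.394), Hox 1 lower of 13 (0.253), immediate early and stress 3 lower of 21 (0.518), and the 2-cell-stage list 0 called of 3 (0.651).

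Other large changes in this comparison fell outside the lists. Stoml1 rose by 2.97 ± 0.29, the fast skeletal muscle light chain gene Mylpf by 2.95 ± 0.36, Ddx49 by 2.70 ± 0.26, the neurofilament gene Nefh by 2.65 ± 0.35 and Ube2s, a ubiquitin-conjugating enzyme of mitosis, by 2.52 ± 0.20. Tug1, a long noncoding RNA, fell by 4.88 ± 0.38, the apelin receptor gene Aplnr by 4.52 ± 1.15, Nrp1 by 3.59 ± 0.61 and Igfbp5 by 3.57 ± 0.61.

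Within hybridisation runs, of which only 1 held both day 7 groups (1 negative and 3 positive arrays), the comparison called 1115 probe sets higher and 625 lower, and 1479 of the 4926 calls remained. Dppa3 stayed higher within the run at 2.96 (adjusted p = 0.00106, the highest of its alternatives, which began at 2.46e-06) and Tfap2c at 2.07 (adjusted p = 0.00469, with a range of 1.80e-05 to 0.0975 over its alternatives). Ddx4 (1.32), Dazl (0.97), Ttr (-3.89) and Afp (-3.07) had the direction of the full model without passing (adjusted p = 0.101, 0.182, 0.197 and 0.218), against ranges over their alternatives of 0.00835 to 0.897, 0.00752 to 0.182, 5.95e-06 to 0.197 and 7.19e-06 to 0.218. Within the run the later germ cell list had a median of 0.95, pluripotency 0.79, endoderm -1.61, endothelium -1.03 and imprinted -1.34. All 5 passed at the preset correlation and not with an estimated one (adjusted p = 0.265 for imprinted and 0.285 for the others). The lone negative array of the run is assumed to vary like the other groups. Leaving out negative array 1 left 838 probe sets higher and 342 lower, and leaving out negative array 2 left 1254 and 528. Without positive arrays 3 and 4, chosen after seeing the data, 3904 of the 4926 calls remained. With the Gapdh ratio as a covariate, also chosen after seeing the data, 1945 remained. Of 88 results for named genes, 33 lost their call within hybridisation runs, 37 and 26 without negative arrays 1 and 2 in turn, 11 without positive arrays 3 and 4 and 26 with the covariate. Scaling moved the median of all probe sets from -0.12 to 0.12 under median centring, which also moved the share of higher calls from 52.1% to 77.7%.

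**Figure D2:**
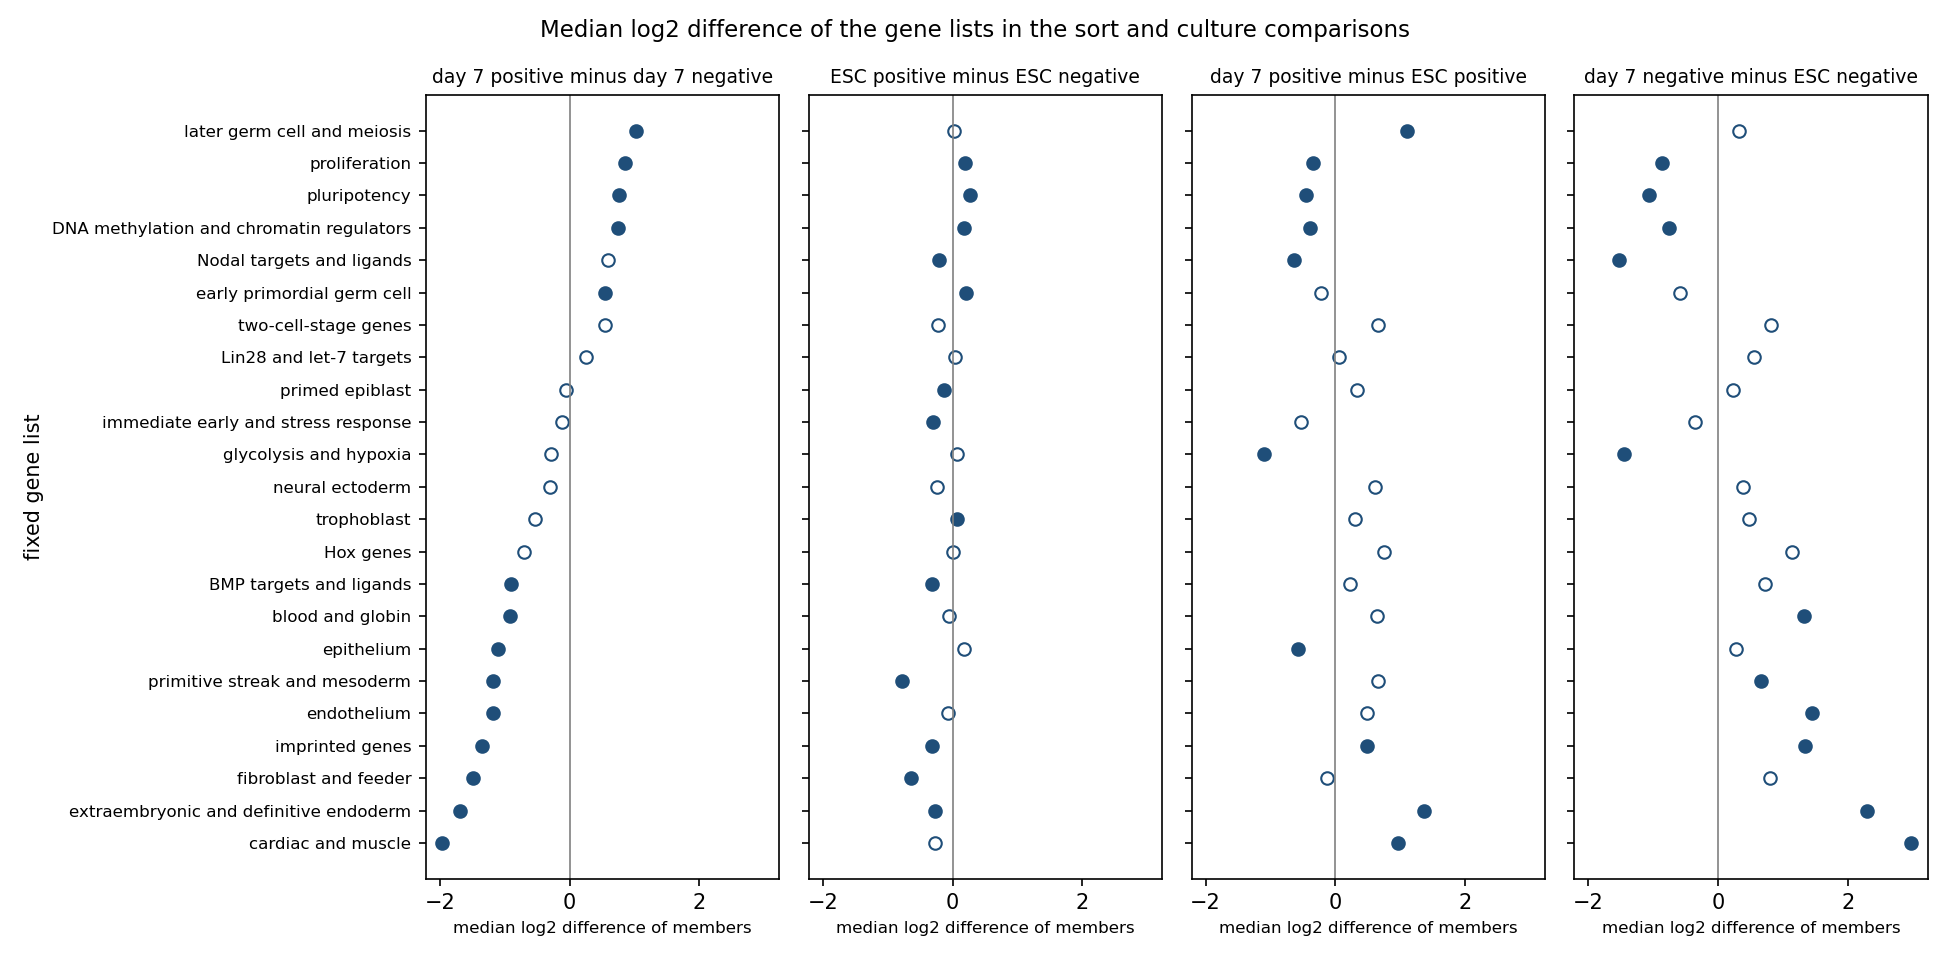
Median log2 difference over the members of each of the 23 fixed gene lists in the sort and culture comparisons, with filled points for lists past the camera test at the preset correlation and open points for the others. At day 7 the later germ cell list had the highest median of the sort, 1.02, and the cardiac list the lowest, -1.97.

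In ESC, Stella-positive cells (n = 2) differed from Stella-negative cells (n = 3) in far fewer probe sets. Dppa3 rose by 2.51 ± 0.27 (limma adjusted p = 0.00168), and it was the only probe set called higher, with 0 called lower. Of 30023 probe sets 834 had an unadjusted limma p under 0.05, a smaller share than the 0.05 given by chance. The test, whose spread is pooled over all groups, may therefore be conservative for this sort. Among the falls nearest the threshold, none past the test, were Tax1bp3 (-1.38), the glutathione peroxidase gene Gpx3 (-1.66), the chromatin gene Hmga2 (-1.66), Sox4 (-1.01), Car2 (-1.60) and the primitive streak factor Mixl1 (-3.67). The nearest rise was Rhox9, a homeobox gene of the X-linked Rhox cluster, at 1.54 (adjusted p = 0.857). Pou5f1 was at 0.21 ± 0.19, Nanog at 0.33 ± 0.28, Sox2 at 0.18 ± 0.22, Tfap2c at 0.23 ± 0.26, Prdm14 at 0.61 ± 0.33 and Ifitm3 at 0.88 ± 0.28, and none of these 6 passed the test.

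As sets, 13 of the 23 lists passed in the ESC sort at the preset correlation and 0 with an estimated one. The mesoderm list was lower (adjusted p = 3.14e-07; adjusted p = 0.154 with an estimated correlation), and 4 of its 23 members, Mixl1, Eomes, Evx1 and Wnt3, were lower when adjusted over the list alone against 0 over all genes. The fibroblast list was lower (2.14e-05; adjusted p = 0.409 with an estimated correlation), as were BMP (2.56e-04; 0.154), imprinted (0.00130; 0.154), immediate early and stress (0.00389; 0.462), endoderm (0.0137; 0.462), primed epiblast (0.0226; 0.409) and Nodal (0.0265; 0.154). The pluripotency list was higher (9.64e-05; adjusted p = 0.409 with an estimated correlation), with 0 of 27 members past the test, as were proliferation (2.56e-04; 0.392), DNA methylation and chromatin (0.00284; 0.170), early primordial germ cell (0.00360; 0.328) and trophoblast (0.0188; 0.154). In the trophoblast list Rhox5 (0.99 ± 0.33), Rhox6 (1.16 ± 0.33) and Rhox9 (1.54 ± 0.35) were higher when adjusted over the list alone.

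Dppa3 lost its call within the hybridisation run that held both sorted ESC groups, with 3 negative arrays and 1 positive array (2.19, adjusted p = 0.0939). It also lost it with only the 5 sorted arrays in the model (adjusted p = 0.0752) and with a constant prior variance (adjusted p = 0.128). Over all its alternatives the adjusted p ran from 5.88e-05 to 0.217. Without Stella-positive ESC array 1 the test called 2 probe sets higher and 2 lower, without array 2 it called 1 and 4, and without Stella-negative ESC array 3 it called 2 and 0. Within that run the mesoderm list had a median of -0.65, against -0.77 in the full model, and the fibroblast list -1.44, against -0.65. The primed epiblast list turned to 0.16 there (adjusted p from 4.52e-05 to 0.409 over its alternatives). The immediate early and stress list (median -0.28) and the Nodal list (-0.17) kept their direction within the run and lost their call. The fibroblast list also turned direction without Stella-positive ESC array 1 (adjusted p = 0.431, with a range of 1.57e-24 to 0.431).

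Across the 13992 genes tested, the day 7 and ESC sorts, which share no array, had a Pearson r of 0.311 and a Spearman rho of 0.298. Of 1421 genes called higher at day 7, 1045 (73.5%) had the same sign in the ESC sort, whatever the size. Of 1243 called lower, 928 (74.7%) did. Their median differences in the ESC sort were 0.14 and -0.20, against 0.99 and -1.35 at day 7. The same-sign share over all genes was not computed. Genes are not independent replicates, so these correlations and shares carry no p-value. Dppa3 was the only gene called higher in both (1 gene, against 0.102 from the product of the counts), and 0 were called lower in both. Both sorts select on the Stella reporter, so this overlap was built in and is no measure of a shared response. The correlation was 0.165 without Stella-positive ESC array 1, and 0.04 with the Gapdh ratio as a covariate.

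The difference between the 2 sorts was itself tested as an interaction, in which 161 probe sets had a higher and 64 a lower sort difference at day 7. The sort difference was more positive at day 7 for Nefh (3.06 ± 0.50), Ddx49 (2.87 ± 0.39), Abcf3 (2.77 ± 0.41), Stoml1 (2.62 ± 0.42) and Abtb1 (2.50 ± 0.51). It was more negative for Hbb-y (-5.51 ± 1.13), Hbb-bh1 (-4.53 ± 0.90), Tug1 (-4.17 ± 0.55), the selenium carrier gene Selenop (-3.71 ± 0.62) and Hand2 (-3.56 ± 0.79). The later germ cell list also had a more positive sort difference at day 7 (median 1.08; adjusted p = 3.82e-06; adjusted p = 0.215 with an estimated correlation). Within hybridisation runs the interaction called 5 and 2 probe sets, and none of these 10 genes kept its call, while all 10 kept their direction. The difference was then smaller in size for 7 of them: Nefh (2.29 ± 0.53), Ddx49 (2.75 ± 0.44), Abtb1 (2.48 ± 0.58), Hbb-y (-4.78 ± 1.1), Tug1 (-3.68 ± 0.71), Selenop (-3.30 ± 0.81) and Hand2 (-2.81 ± 0.87). It was larger for Abcf3 (2.80 ± 0.49), Stoml1 (3.03 ± 0.49) and Hbb-bh1 (-4.61 ± 1.25), with a larger SE than in the full model for 9 of the 10. The 10 genes were named for large differences on these same arrays, so a kept direction adds little. Without Stella-positive ESC array 2, 1 of the 10 kept its call. Median centring gave 20 and 10 probe sets (30 of the 225 calls remained), a constant prior variance 3 and 6 (8 remained) and the Gapdh ratio as a covariate 1069 and 1721 (123 remained). The higher count was 40, 34 and 29 without Stella-negative ESC arrays 1, 2 and 3 in turn, 80 and 2 without Stella-positive ESC arrays 1 and 2, 9 and 22 without negative day 7 arrays 1 and 2, and 105, 94, 65 and 278 without positive day 7 arrays 1 to 4. The lower counts ran from 2 without Stella-positive ESC array 2 to 119 without positive day 7 array 4.

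Stella-positive day 7 cells (n = 4) were set against Stella-positive ESC (n = 2) to describe the change over culture within the reporter-positive fraction. Dazl rose by 2.98 ± 0.34 (adjusted p = 6.50e-05) and Stra8, needed for entry into meiosis, by 3.11 ± 0.40, with Gtsf1, a piRNA pathway gene, at 2.04 ± 0.38. Of 23 later germ cell genes 11 rose and 0 fell (15 adjusted over the list alone; list adjusted p = 1.95e-06; adjusted p = 0.314 with an estimated correlation). Dppa3 itself was at -0.35 ± 0.26 (adjusted p = 0.380). Glycolytic and hypoxia genes were lower: 11 of 19 fell and 0 rose (12 lower and 1 higher adjusted over the list alone), with lactate dehydrogenase Ldha at -2.85 ± 0.30, phosphofructokinase Pfkl at -2.99 ± 0.35 and the mitophagy gene Bnip3 at -3.51 ± 0.46 (list adjusted p = 7.45e-11; adjusted p = 0.296 with an estimated correlation). In all, 2508 probe sets were higher and 2228 lower. The actin ratio was 2.04 to 5.16 in these day 7 cells and 1.12 to 1.16 in the ESC they were set against.

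In the same comparison Afp and Ttr rose by 5.08 ± 1.29 and 5.06 ± 1.34, and 12 of 28 endoderm genes rose (16 adjusted over the list alone; list adjusted p = 1.03e-05; adjusted p = 0.314 with an estimated correlation). Pluripotency genes had 10 of 27 lower and 2 higher, with Pou5f1 at -1.09 ± 0.18 and Klf2 at -1.15 ± 0.18, and the Nodal list had 6 of 12 lower, with Lefty1 at -2.49 ± 0.22 (list adjusted p-values 0.00229 and 6.02e-04; adjusted p = 0.661 and 0.0870 with an estimated correlation). Of the early germ cell genes Tfap2c rose by 1.28 ± 0.25, Ifitm3 and the surface protein gene Cd9 fell by 1.14 ± 0.26 and 1.09 ± 0.25, and Prdm1, Prdm14, Kit and Dnd1 did not pass. Nor did Ddx4 of the later germ cell list or Nanog and Sox2 of the pluripotency list. Also past the set test were proliferation (8 of 23 lower, 4.42e-04), imprinted (7 of 25 higher, 0.0184), DNA methylation and chromatin (5 lower and 2 higher of 22, 0.0180), epithelium (3 of 18 lower, 0.0230) and cardiac (3 of 16 higher, 0.0391). With an estimated correlation these had adjusted p = 0.365, 0.314, 0.314, 0.661 and 0.661. Susd5 (4.40 ± 0.35) and the Y-linked Uba1y (3.15 ± 0.27) were among the largest rises, and Upp1 (-3.36 ± 0.32), the monocarboxylate transporter Slc16a3 (-3.12 ± 0.36) and Prmt1 (-2.80 ± 0.24) among the largest falls.

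Stella-negative day 7 cells (n = 2) differed most from their ESC counterparts (n = 3), with 5547 probe sets higher and 4514 lower. Ttr and Afp rose by 10.02 ± 1.41 and 9.0 ± 1.36, Hbb-y and Hbb-bh1 by 7.82 ± 0.82 and 6.54 ± 0.65, and the retinol carrier gene Rbp4 by 6.47 ± 0.90. Of 28 endoderm genes 24 rose (25 adjusted over the list alone), of 16 cardiac genes 13, with cardiac actin Actc1 at 5.20 ± 0.61, of 16 endothelial genes 10, with Cdh5 at 2.70 ± 0.48, and of 16 blood genes 8, with 0 lower in each. Of 25 imprinted genes 15 rose (16 adjusted over the list alone), with Dlk1 at 4.57 ± 0.46 and Meg3 at 3.43 ± 0.26, and in the mesoderm list 10 rose and 1 fell of 23. The adjusted p-values of these 6 lists were 5.23e-10, 6.24e-05, 0.00581, 0.00353, 4.23e-05 and 0.0381, and adjusted p = 0.105, 0.289, 0.352, 0.0797, 0.0797 and 0.489 with an estimated correlation.

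In the same cells 17 of 27 pluripotency genes fell (18 adjusted over the list alone), with Pou5f1 at -2.60 ± 0.19, and 15 of 23 proliferation genes fell and 1 rose (17 and 1), with Mcm3 at -1.86 ± 0.17, though 1 other Mcm3 probe set was called higher. DNA methylation and chromatin regulators had 12 of 22 lower and 3 higher, with Prmt5 at -2.74 ± 0.22 and Dnmt3l at -2.59 ± 0.30, and glycolysis genes 13 of 19 lower and 1 higher, with Pfkl at -3.70 ± 0.37. The Nodal list had 9 of 12 lower and 1 higher, with Lefty1 at -3.70 ± 0.23. Of the 73 list calls over all 7 comparisons, this was the only 1 that held with an estimated correlation (adjusted p = 5.37e-05; adjusted p = 0.0436 with an estimated correlation). The other 4 lists had adjusted p-values of 2.26e-07, 6.82e-09, 4.51e-05 and 9.96e-06, and adjusted p = 0.317, 0.132, 0.0797 and 0.289 with an estimated correlation. Dppa3 fell by 1.1 ± 0.27, while Dazl rose by 2.0 ± 0.36. Ddx4 was called lower, as were Ifitm3, Dnd1 and Cd9 of the early germ cell list. With the Gapdh ratio as a covariate these calls were lost and the differences turned upward (0.82, 1.19, 0.020 and 0.47). The actin ratio was 5.48 and 5.85 in these cells and 1.12 to 1.17 in the ESC they were set against.

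Both culture comparisons are confounded with hybridisation day, since no day held day 7 and ESC arrays, so day and culture cannot be told apart. With the Gapdh ratio as a covariate, an alternative chosen after the data were seen, the positive comparison had 678 probe sets higher and 332 lower and the negative comparison 1721 and 907. Of the calls without it, 459 of 4736 and 1100 of 10061 remained. That covariate turned the direction of 16 of the named genes, among them Dazl and Ddx4 in the negative comparison (-0.34 and 0.82). Against unsorted ESC the counts were 972 and 1123, and 1871 and 2289, and 12 named genes turned direction in the positive comparison, among them Dppa3 (1.53), Susd5 (-0.63), Pou5f1 (0.14) and Prmt1 (0.53). In the positive comparison the epithelium list turned upward and passed with the covariate (adjusted p = 0.00284, with a range of 0.00211 to 0.785 over its alternatives), and the proliferation list turned against unsorted ESC (adjusted p = 0.893, with a range of 1.55e-05 to 0.893). In the negative comparison the glycolysis list turned with the covariate (adjusted p = 0.375, with a range of 2.06e-07 to 0.375). Under median centring the median of all probe sets moved from 0.16 to -0.28 in the positive and from 0.24 to -0.36 in the negative comparison, and the share of higher calls from 53.0% to 12.1% and from 55.1% to 16.8%. Quantile normalization gave 44.1% in the positive and 42.9% in the negative comparison. Without Stella-positive ESC arrays 1 and 2 in turn, the positive comparison called 1016 and 621 probe sets higher and 1060 and 580 lower, and without negative day 7 arrays 1 and 2 the negative comparison called 2406 and 2850 higher and 2770 and 3099 lower. Across 13992 genes the culture comparisons had r = 0.684 and rho = 0.669, with 835 genes higher in both (234.2 from the product of the counts), 718 lower in both (148.9) and 3 called in opposite directions. The genes higher in both numbered 371 and 273 without Stella-positive ESC arrays 1 and 2, and 535 and 554 without negative day 7 arrays 1 and 2.

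Unsorted ESC (n = 2) were compared with each sorted ESC fraction to place the starting population. The matrix proteoglycan gene Dcn rose in unsorted cells by 3.47 ± 0.55 over Stella-negative ESC and 4.37 ± 0.60 over Stella-positive ESC, and Postn by 3.19 ± 0.66 over the negative fraction. Tnc and the hyaluronan receptor gene Cd44 rose by 4.69 ± 1.0 and 4.38 ± 0.76 over the positive fraction. Of 23 fibroblast and feeder genes, 4 rose against the negative and 7 against the positive fraction (13 and 19 adjusted over the list alone; list adjusted p = 5.29e-09 and 3.72e-13; adjusted p = 0.923 and 0.408 with an estimated correlation). Susd5 (4.55 ± 0.37 and 5.04 ± 0.41) and Myo1f (4.52 ± 0.41 and 4.99 ± 0.45) had the largest rises, and Hmox1, the stress-induced heme oxygenase gene, was at -3.67 ± 0.46 and -3.55 ± 0.50, with Prmt1 at -3.04 ± 0.26 and -3.33 ± 0.28, all called. In all, 328 probe sets were higher and 281 lower than in Stella-negative ESC, and 574 and 468 than in Stella-positive ESC.

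Glycolysis and hypoxia genes were lower in unsorted cells as a set (adjusted p = 0.00155 and 5.23e-04 against the negative and positive fractions; adjusted p = 0.923 and 0.503 with an estimated correlation), with 1 and 3 of 19 members lower, or 8 and 6 adjusted over the list alone. That adjustment also gave 2 and 0 members higher. The proliferation list was lower as a set (0.0287 and 7.44e-05; adjusted p = 0.923 and 0.464 with an estimated correlation), with 1 of 23 members lower in each comparison, or 1 and 4 adjusted over the list alone. The Hox list was higher as a set (0.0183 and 0.0197; adjusted p = 0.923 and 0.496 with an estimated correlation), but in limma 0 of its 13 members passed in either comparison, also over the list alone, with 6 and 3 higher at an unadjusted p under 0.05. Against the positive fraction alone the mesoderm (0.00909), imprinted (0.00909) and endoderm (0.0197) lists were higher and the chromatin list (0.0197) lower; with an estimated correlation these had adjusted p = 0.503, 0.408, 0.707 and 0.461. In limma 0 of 23 mesoderm genes passed (4 higher at an unadjusted p under 0.05), 4 of 25 imprinted and 2 of 28 endoderm genes were higher, and 4 of 22 chromatin genes were lower and 1 higher. On the scale from the negative (0) to the positive fraction (1), Dppa3 placed the unsorted arrays at 0.228 and 0.272. Over the 200 probe sets with the smallest p in the ESC sort the positions were -0.297 and 0.215. Over the probe sets called without Stella-positive ESC array 1 they were -0.129 and -0.237, and without array 2 they were -0.357 and 0.188.

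Unsorted arrays shared no hybridisation day with sorted ones, so day and sorting cannot be told apart here. With the run as a random block, 27 probe sets were higher and 16 lower than in negative ESC, and 120 and 74 than in positive ESC. Without unsorted array 1 the higher counts were 28 and 29. The higher count against the negative fraction was 134 without Stella-negative array 1 and 82 without array 2; against the positive fraction it was 112 and 242 without Stella-positive arrays 1 and 2. Without Stella-positive day 7 array 4, which widens the shared spread, the higher counts were 714 and 1096. Under median centring the share of higher calls moved from 53.9% to 33.9% and from 55.1% to 26.98%, with the median of all probe sets at -0.11 and -0.15.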

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

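The test of 3'-biased RNA over all probe sets higher at day 7 was set out before its result was seen, while the tests of the dim arrays, of the probe sets higher without those arrays, of the germ cell list, of fibroblasts, of hybridisation day and of the glycolysis reference were chosen only after the result was seen, as were the counts of interaction genes called with the run as a block or without single arrays and the alternatives with the Gapdh ratio as a covariate and without positive arrays 3 and 4.

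Among the 4 Stella-positive day 7 arrays, 147 measures were examined for 1 array far from the others, by its gap to the nearest array divided by the range of all 4. This share passed Dixon's 95% critical value for 6 genes: Tex19.1 (0.976), Sox4 (0.965), Ncam1 (0.953), Ccnb2 (0.925), Lefty1 (0.866) and Smad6 (0.863). Chance gives about 1 in 20 such results, and 6 of 147 is no more than that.

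The effect of the Stella sort differed between day 7 and ESC, by the interaction test, for 161 probe sets in the positive and 64 in the negative direction. Of the 18 genes given here, 1 (Ube2s, adjusted p = 0.0434) passed with the hybridisation run as a block and 2 without Stella-positive ESC array 2, and 0 turned direction. Among named genes the day 7 sort difference minus the ESC sort difference was 3.06 for Nefh, 2.87 for Ddx49, 2.77 for Abcf3, 2.62 for Stoml1, 2.50 for Abtb1, 2.25 for Ube2s, 1.95 for Dnmt3l, 1.77 for Tfap2c, 1.51 for Pou5f1, 1.20 for Ccnb2, 1.17 for Mcm6 and 1.09 for Mcm3. It was -5.51 for Hbb-y, -4.53 for Hbb-bh1, -4.17 for Tug1, -3.71 for Selenop, -3.56 for Hand2 and -3.35 for Col3a1. All 18 genes had passed the interaction test on these same arrays, so a kept direction was likely beforehand. Of the gene lists the later germ cell list had a median difference of 1.08, Nodal 0.76, pluripotency 0.75, proliferation 0.61 and DNA methylation and chromatin 0.53. The cardiac list had a median of -1.84, endoderm -1.35, endothelium -1.20, imprinted -0.99, epithelium -0.705, fibroblast -0.69, blood -0.65 and BMP -0.54. These 13 lists passed at the preset correlation and 0 passed with an estimated one (adjusted p from 0.0846 to 0.607). With the hybridisation run as a block 11 of the 13 passed at the preset correlation, while BMP lost its call (adjusted p = 0.279, range over its alternatives 0.00503 to 0.372) and the fibroblast list turned direction (median 0.10, adjusted p = 0.680, range 4.39e-07 to 0.953), as it did without Stella-positive ESC array 2 (adjusted p = 0.953).

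The rise of 2564 probe sets and of the later germ cell list in Stella-positive day 7 cells was weighed against 3'-biased RNA on the negative arrays and against the dim positive arrays 3 and 4. On positive arrays 3 and 4, whose actin ratios of 4.89 and 5.16 lay near the 5.48 and 5.85 of the negative arrays, the median fall from arrays 1 and 2 was -4.55% of their excess of 1.02 over the negatives, but arrays 3 and 4 entered the choice of these probe sets, so this value excludes nothing. Over the 2831 probe sets called higher without arrays 3 and 4, a choice that favours a fall on them, the fall was 14.9% of an excess of 1.04, with 7.87% for array 3 and 20.9% for array 4. The germ cell list held 95.3% of its median on arrays 3 and 4 (0.97 against 1.02 over all 4, which include them). Without those arrays 81.7% of the higher probe sets stayed called, which argues against the dim arrays as the whole cause. For RNA quality these values cannot decide. Arrays 3 and 4 were scaled 3.62-fold and 12.4-fold, against 1.27-fold and 1.47-fold for arrays 1 and 2. Such scaling can lift dim signal where a fall was looked for. Their Gapdh ratios (1.65 and 2.09) also stayed below those of the negative arrays (3.03 and 3.18). With the Gapdh ratio as a covariate 1945 of the 4926 calls in both directions remained. Its slope rests mainly on the 4 positive day 7 arrays, where the 2 highest ratios belong to the 2 dimmest arrays. A biological difference between reporter-positive and reporter-negative cells, which the design names, stays open as untested.

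The fibroblast and feeder list was higher in unsorted ESC, with medians of 1.47 over the negative and 1.93 over the positive fraction. Fibroblasts such as feeder cells are a candidate source. Of 23 tested members 13 (56.5%) were higher on both unsorted arrays than on all 5 sorted ESC arrays. The share was 18.96% for all probe sets and is 4.76% for a random order. By cut-offs set after the result was seen, the 56.5% neither bore out nor excluded fibroblasts. The most abundant members stood at 4635 against 3191 scaled signal for Fn1, 3812 against 2530 for Vim and 1688 against 566.9 for Acta2 in unsorted against sorted ESC. None of these was among the 13. The most abundant of the 13 were Dcn (692.4 against 45.0), Thy1 (819.8 against 190.1) and Col1a2 (795.3 against 102.8). Of the 23 members 11 also lay above the array median on all sorted ESC arrays. A reporter sort would take reporter-negative fibroblasts out of the positive fraction, and out of the negative fraction only with a further gate, which is not given in the sources used here. Unsorted and sorted arrays shared 0 hybridisation days, so fibroblasts, hybridisation day and an untested biological difference between unsorted and sorted cells cannot be told apart.

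The glycolysis and hypoxia list was lower at day 7 than in sorted ESC, with a median of -1.37 over both fractions. Against unsorted ESC the median was -0.72, or 52.6% of that difference, which neither excludes nor bears out a level particular to the sorted ESC arrays. RNA quality also stays open. With the Gapdh ratio as a covariate the list turned direction in negative cells (camera adjusted p = 0.375, range over its alternatives 2.06e-07 to 0.375). That covariate cannot separate RNA quality from dim signal, because its slope rests mainly on the 4 Stella-positive day 7 arrays. A level particular to the sorted arrays and a change with culture, which the design names and which was not tested apart from hybridisation day, cannot be told apart because no day held both day 7 and ESC arrays.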

How the results depend on the processing

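The tests with Stella-positive day 7 arrays 3 and 4 both left out, with the Gapdh 3'/5' ratio as a covariate, with the numbers of the array headers as a block, with a crossed block, with an estimated correlation within hybridisation runs and with unsorted ESC as the reference were chosen only after the results were seen; the others were planned. Counts below are of probe sets called higher and then lower, unless 1 direction is named. They are given where they lay more than 1.5 times from those of the full model: 2564 and 2362 for the day 7 sort, 1 and 0 for the ESC sort, 2508 and 2228 for culture in positive cells, 5547 and 4514 for culture in negative cells, 161 and 64 for the interaction, 328 and 281 for unsorted against negative ESC, and 574 and 468 for unsorted against positive ESC. Except where a value or the construction of an alternative shows it, the cause of a change was not tested. MAS5 signal near background limits the dim genes, and no present call was used here. The constant c shrinks differences of probe sets near it. The scaled arrays kept unlike medians, with the median of all probe sets at 0.16 and 0.24 in culture of positive and negative cells. Dim probe sets can therefore also be shifted upward at day 7, which would overstate their rise. Groups of 2 arrays limit the rest, since leaving out 1 of them leaves a lone array that is assumed to vary like the other groups. The list test was not run with the run as a random block, and it rests on 1 probe set per gene in any case. All other alternatives set out before the data were examined were run.

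Of 302 results for named genes, 293 stayed on the same side of the threshold and in the same direction with c at 1/50 of the trimmed mean, 299 with c at 1/4, 285 with no filter, 299 with the stricter filter, 289 under quantile normalization and 264 under median centring. The count was 277 with only the groups compared, 266 with a constant prior and 289 with array weights. None of these 9 alternatives turned a named gene or any of the 73 list calls; between 66 and 73 of the list calls stayed past the test under each of them. With an estimated correlation 1 list call stayed and 72 were lost. Over the 13 arrays left out in turn, named genes gave 3650 unchanged results, 269 that lost and 7 that gained a call, and 0 that turned. The list calls gave 898 unchanged, 48 lost and 3 turned.

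With c at 1/50 the interaction had 31 lower. Without a filter it had 79 and 35, and unsorted against negative ESC had 212 higher. Under quantile normalization the interaction had 385 and 147. Median centring gave 922 lower in the day 7 sort, 599 and 4343 for culture in positive cells, 1634 and 8103 in negative cells, 20 and 10 for the interaction, 77 and 150 for unsorted against negative ESC, and 136 higher against positive ESC. It moved the genes called in both culture comparisons from 835 higher and 718 lower to 161 and 1651. With only the groups compared in the model, which leaves fewer arrays to estimate the spread, the day 7 sort had 1313 lower, culture in positive cells 1479 and 1445, unsorted against negative ESC 536 higher, and unsorted against positive ESC 53 and 34. The ESC sort then had 0 higher in limma, with Dppa3 at 2.51 (adjusted p = 0.0752).

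A constant prior variance also left 0 higher in the ESC sort and 0 genes higher in both sorts, with Dppa3 at 2.51 (limma adjusted p = 0.128). The full model had 834 probe sets at an unadjusted p under 0.05 in this sort, a smaller share than chance gives. Over all its alternatives the adjusted p of Dppa3 in the ESC sort ran from 5.88e-05 to 0.217. The constant prior gave 3 and 6 for the interaction, 66 and 41 for unsorted against negative ESC, 109 and 48 against positive ESC, and 463 genes lower in both culture comparisons. Array weights, lowest for the dimmest arrays (0.224 for positive day 7 array 4), gave 1 lower in the ESC sort, 596 and 290 for the interaction, 1034 and 935 for unsorted against negative ESC and 1155 and 861 against positive ESC. With 1 probe set per gene, which tests fewer by construction, the counts were 1511 and 1350, 1241 and 926, 2650 and 2249, 92 and 28, 176 and 149, and 343 and 285, in the order of the comparisons above without the ESC sort. With the median of a gene's probe sets, Grhl2 (-0.21) and Smad7 (0.23) turned in culture of positive cells and Lin28a (0.30) in negative cells, none past the test. Of the 302 results for named genes 32 then lost and 1 gained a call. The losses included 16 in culture of positive cells, 8 in the day 7 sort and 4 in the interaction. Over the 200 smallest p-values of the ESC sort unsorted array 1 moved from 0.228 to -0.297 on the scale from negative to positive ESC.

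The hybridisation run as a block gave 1115 and 625 in the day 7 sort, 5 and 2 for the interaction, 27 and 16 for unsorted against negative ESC, 120 and 74 against positive ESC, and 538 genes higher in both culture comparisons. The ESC sort then had 0 higher and the sorts shared 0 genes, with Dppa3 at 2.19 (adjusted p = 0.0939). Under this block the primed epiblast list turned in the ESC sort (adjusted p = 0.345, range over its alternatives 4.52e-05 to 0.409), as did the fibroblast list in the interaction (adjusted p = 0.680, range 4.39e-07 to 0.953). Of the 302 results for named genes 67 lost and 1 gained a call under this block.

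The replicate numbers of the titles gave no sign of pairing: deviations of same-numbered arrays from their group means correlated between -0.131 and 0.0741, and no comparison had 3 pairs. In a group of 2 arrays the deviations mirror each other, so these correlations can show little. With the title numbers as a replicate block the interaction had 30 and 29, unsorted against negative ESC 496 and 437, and against positive ESC 1021 and 804. This block moved no other count by over 1.5 times. The array headers give other numbers than the titles on most arrays, and which numbering is right is not known. No such correlations were computed for the header numbers. With the header numbers as the block the ESC sort had 0 higher and the sorts shared 0 genes, with Dppa3 at 2.67 (adjusted p = 0.217). The interaction then had 4 and 36, culture in positive cells 89 and 97 (185 of its 4736 calls remained, and 47 of 81 named genes lost their call), unsorted against negative ESC 63 and 38, and against positive ESC 1 and 2, and 52 genes were higher and 41 lower in both culture comparisons. The primed epiblast list turned in the ESC sort under that block (adjusted p = 0.149). A crossed block gave 1549 and 1132 for unsorted against positive ESC.

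With the Gapdh ratio as a covariate, which was 0.803 to 0.869 on ESC and 1.23 to 3.18 on day 7 arrays, culture in positive cells had 678 and 332, in negative cells 1721 and 907, the interaction 1069 and 1721, unsorted against negative ESC 799 and 635, and against positive ESC 1124 and 859. The correlation of the sorts was 0.0443 instead of 0.311 and that of the culture comparisons 0.885 instead of 0.684, with 339 genes higher and 93 lower in both. In culture of positive cells Spint2 (0.16) and Epcam (0.86) turned. In culture of negative cells Zmynd19 (0.99), Trh (0.25), Sfn (0.93), Cd9 (0.47), Dazl (-0.34), Ddx4 (0.82), Stmn2 (0.27), Pax3 (-0.055), Hoxb3 (-0.10), Hoxb4 (-0.86), Mycn (0.71), Twist1 (-0.44), Ifitm3 (1.19) and Dnd1 (0.020) turned. None of these 16 was past the test with the covariate. The list tests turned for early primordial germ cell genes in the day 7 sort (adjusted p = 0.810, range over its alternatives 8.92e-05 to 0.810), epithelium in culture of positive cells (0.00284, range 0.00211 to 0.785) and glycolysis in culture of negative cells (0.375, range 2.06e-07 to 0.375). Of the 302 results for named genes 181 were unchanged and 105 lost their call.

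Without positive day 7 arrays 3 and 4 the interaction had 323 and 173, unsorted against negative ESC 1074 and 883, and against positive ESC 1497 and 1071. Against unsorted ESC, culture in positive cells had 972 and 1123 and in negative cells 1871 and 2289. In positive cells Susd5 (-0.63), Prmt1 (0.53), Pou5f1 (0.14), Sox4 (-0.67), Cdh2 (-1.16), Nes (-1.11), Car2 (-0.21), Tet2 (-0.61), Hmga2 (-0.34), Hmox1 (0.89), Epcam (0.047) and Dppa3 (1.53) then turned, of which Nes and Dppa3 were past the test, and the proliferation list turned (adjusted p = 0.893, range 1.55e-05 to 0.893).

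Leaving out each array in turn gave 838 to 2990 higher and 342 to 3102 lower in the day 7 sort, lowest without negative day 7 array 1 and highest without positive array 4. The ESC sort ran from 1 to 2 higher, with 2 without Stella-negative array 3 or Stella-positive array 1, and from 0 to 4 lower, with 2 without Stella-positive array 1 and 4 without array 2. Culture ran from 621 to 2785 and from 580 to 2390 in positive cells, lowest without Stella-positive ESC array 2, and from 2406 to 7126 and from 2770 to 5207 in negative cells, lowest without negative day 7 array 1. The interaction ran from 2 to 278 and from 2 to 119, lowest without Stella-positive ESC array 2. Unsorted ESC had 28 to 714 and 16 to 597 against the negative fraction and 29 to 1096 and 19 to 799 against the positive fraction, lowest without unsorted array 1. Apart from the ESC sort, these maxima came without positive day 7 array 4. The correlation of the sorts ran from 0.165 without Stella-positive ESC array 1 to 0.358, and from 0 to 2 genes were lower in both, the most without Stella-positive ESC array 2. Genes in both culture comparisons ran from 273 to 1025 higher and from 238 to 758 lower, lowest without Stella-positive ESC array 2. The position of unsorted array 1 ran from -0.357 to 0.346 and that of array 2 from -0.237 to 0.352, lowest without Stella-positive ESC arrays 2 and 1. The adjusted p of the fibroblast list ran from 1.57e-24 to 0.431 in the ESC sort and from 4.39e-07 to 0.953 in the interaction, and that of the primed epiblast list from 4.52e-05 to 0.402 in the ESC sort. Dppa3 kept its call each time, at 3.06 to 3.45 in the day 7 sort and 2.19 to 2.83 in the ESC sort.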

Other observations

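All tests in this part were chosen only after the values were seen: 3 gene lists, of interferon-induced, Y-linked and X-linked Rhox genes, were drawn up then, and each is given.

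Of 10 tested interferon-induced genes, 5 were higher and 0 lower in unsorted ESC than in Stella-positive ESC (list median 2.33), and 2 were higher and 0 lower than in Stella-negative ESC (median 1.35). At an unadjusted p under 0.05 in limma the counts were 8 and 7, and no set test was run on this list. Rtp4, a receptor transporter gene induced by interferon, was higher by 4.15 ± 0.56 over positive ESC (limma adjusted p = 0.00190) and 2.87 ± 0.51 over negative ESC (adjusted p = 0.00947). Ifit1, an antiviral RNA-binding protein gene, was higher by 2.63 ± 0.56 (adjusted p = 0.0194) and 2.37 ± 0.51 (adjusted p = 0.0246). Ifit3 (3.07), Usp18 (3.06) and Ifi27 (2.64) passed against positive ESC, with adjusted p-values of 0.0339, 0.0223 and 0.00941. Against negative ESC they were also higher, by 2.28, 2.14 and 1.27, without passing (adjusted p = 0.0959, 0.0825 and 0.149). Under median centring, which moved these list medians to 2.08 and 1.18, the counts were 4 and 1. In the ESC sort the list had a median of -0.85, with 0 members past limma's test and 3 at an unadjusted p under 0.05. In the day 7 sort Ifit1 was lower (-1.483, limma adjusted p = 0.0471). Rtp4 (1.505, limma adjusted p = 0.0457) and Ifi27 (2.12, adjusted p = 0.00311) were higher in Stella-positive day 7 cells than in Stella-positive ESC. The fibroblast and feeder list was also higher on the unsorted arrays, with medians of 1.93 over positive and 1.47 over negative ESC. The unsorted arrays had a hybridisation day of their own, so day and sorting cannot be told apart for these genes.

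The 3 Rhox genes tested, homeobox genes of a cluster on the X chromosome, rose at day 7 in Stella-positive cells: Rhox5 by 2.19 ± 0.31, Rhox6 by 1.75 ± 0.32 and Rhox9 by 1.06 ± 0.33 (adjusted p = 0.0374). In the ESC sort their median was 1.16, with 0 past limma's test over all genes and 3 at an unadjusted p under 0.05, and in the interaction 0 passed, with 1 at an unadjusted p under 0.05. Of 5 Y-linked genes, Eif2s3y (1.23 ± 0.25, limma adjusted p = 0.00374) and Uba1y (1.39 ± 0.27, adjusted p = 0.00257) were higher in positive than in negative day 7 cells. Kdm5d (-0.42), Usp9y (-0.28) and Uty (0.05) did not pass, and the list median was 0.05. The X-linked gene Xist had log2 values of 9.33 and 9.28 on negative and 7.62 to 8.41 on positive day 7 arrays. It stood at 9.56 and 9.18 on unsorted and at 7.82 to 8.84 on sorted ESC arrays. The cause of these differences was not tested. Uba1y was also higher at day 7 than in ESC in both fractions (3.15 ± 0.27 in positive and 2.40 ± 0.28 in negative cells). Kdm5d was at 1.44 ± 0.52 in negative cells (adjusted p = 0.0402), where quantile normalization and median centring each left 1 of the 2 Y-linked calls. The ESC sort, the interaction and the unsorted comparisons called 0 Y-linked genes in limma, with 0 or 1 at an unadjusted p under 0.05 in each.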
